A study of Oryza sativa with 4 samples.

How the data were processed

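DAP-seq (DNA affinity purification sequencing) captures naked, fragmented genomic DNA on a purified or in vitro expressed transcription factor and sequences what is retained. Per the labels' protocols, leaf genomic DNA of the rice cultivar Nipponbare was extracted with phenol and chloroform, and HALO-tagged bZIP proteins were made in a rabbit reticulocyte expression system. HALO is a protein tag that links covalently to beads. The 4 libraries were OsbZIP42 (also labelled HBF1), OsbZIP69 (also labelled FD4), OsbZIP77 (also labelled FD1) and HALO fused to glutathione S-transferase (HALO-GST), which has no DNA-binding domain of a transcription factor and serves as the negative control. Groups were taken from the sample titles, with 1 library per group.

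Reads were aligned with Bowtie2 2.2.8, per the submitters' processing notes. The genome build is not given in the sources used here. The names of the deposited files record that peaks were called with GEM, a peak caller that also models sequence motifs, and that the 3 bZIP libraries were called against a negative control while HALO-GST was called without one. The deposited name of the OsbZIP77 list lacks the word for reticulocyte lysate that the other 3 names carry, so its expression system rests on the protocol label alone. A word in these names is read here as multiply mapped reads left out, which no label states; numbers of peaks per Mb are not corrected for sequence lost that way. Each deposited list was called on a single library, and every deposited interval is 201 bp wide with its centre in the middle. The authors' signal value per peak fills the signal column of the narrowPeak layout; neither its unit nor a scaling between libraries is given in the sources used here, so ratios of signal between libraries are in unmatched units. The deposited peak score ran up to 1000 in each list and was tied to the signal by a straight line below that limit, to within 0.939 score units in the 3 bZIP lists. The deposited −log10 q-values start at 2.00 in every list, a q-value limit of 0.01. The deposited −log10 p-values were 0 throughout the HALO-GST list and were used nowhere. Read numbers per library were not analysed here, so the depth behind a peak is unknown and no interval that needs it is given. Intervals on shares of peaks are exact (Clopper-Pearson) 95% intervals that cover the counting of peaks alone, not variation between libraries. A count of 0 is given instead with the limit of 3 counts of the total.

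Coordinates are 1-based, in the build the authors used. The gene table at hand belongs to another assembly (ASM3414082v1): its genes extend past the last peak by 4.55 Mb on chromosome 9 and by 2.10 Mb on chromosome 11. Peaks were therefore not assigned to genes, exons, introns or UTRs, and no sequence was searched. The planned analyses of genomic distribution, ACGT motifs, k-mers, fixed gene lists and target genes were not run. The lists of florigen and PEBP genes, AP1 and SEPALLATA MADS-box genes, other floral meristem genes, flowering-time genes, 14-3-3 and bZIP genes, ABA genes, gibberellin genes and housekeeping genes accordingly have no result here. The rule for named genes was applied to sites instead: the 5 peaks with the highest signal in each bZIP list that lay more than 100 bp from any HALO-GST peak, and the 10 sites in all 3 bZIP lists with the best worst rank, where a rank is a share of the list's length.

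A peak counted as shared when a centre of the other list lay within 100 bp. The share of the shorter list, or of the bZIP list in comparisons with HALO-GST, was compared with 1000 shuffles that placed its centres uniformly on the same chromosome, up to the furthest peak end in any list, and a share was called when no shuffle reached it. The planned shuffles that keep promoter status needed an annotation and were replaced by these. A stricter null, added after seeing the data, moved each peak by 5 to 50 kb to either side. Sharing in the upper and lower 50% of a list by signal was compared with Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 4 comparisons. The co-occurrence of OsbZIP69 and OsbZIP77 was measured as a Mantel-Haenszel odds ratio over OsbZIP42 peaks in 20 strata of signal. For this measure, the chromosome test and the comparison by local density, an OsbZIP42 peak counted as shared only when it was the nearest to a peak of the other list within 100 bp, which gave 1075 OsbZIP42 peaks for OsbZIP69 and 1980 for OsbZIP77. Elsewhere every OsbZIP42 peak within 100 bp counted, 1227 and 2209. Spearman correlations of signal across sites came with 1000 bootstrap draws of sites and 100000 permutations; sites within a library are not independent replicates. These last measures, and the chromosome test, were chosen after seeing the data. All tests compare peak lists of single libraries and say nothing of the spread between repeat libraries.

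The overlap script was run on simulated lists as a check of its code only, against 200 shuffles each. Lists with 200 planted shared peaks returned 200 of them and were called, for the OsbZIP69-sized list of 1107 and the OsbZIP77-sized list of 2059. These peaks were planted at OsbZIP42 centres, moved by less than the 100 bp window, so their recovery was fixed in advance. Lists with 0 planted peaks were not called. They were made by the same uniform placement as the shuffles, so a call was unlikely from the outset. The check therefore does not measure how the overlap call behaves on real lists. Alternatives were other windows (50, 200 and 500 bp), the upper 50% of each list by q-value, lists of equal length, merged neighbouring centres, and the removal of peaks near HALO-GST peaks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.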

Results

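To map where FD-related bZIP proteins of rice bind, 3 members of the family and a HALO-GST control were each incubated with Nipponbare genomic DNA, and the retained DNA was sequenced. The proteins were OsbZIP42 (HBF1), OsbZIP69 (FD4) and OsbZIP77 (FD1). bZIP proteins bind DNA as dimers through a basic region followed by a leucine zipper, and FD-type bZIPs are the DNA-binding partners of florigen, the mobile flowering signal. Each group held 1 library without replicates, so every difference between libraries below lacks a replicate check. Signal denotes the authors' own value per peak and ranks peaks within a list; its scale was not matched between libraries, and the depth of each library is unknown.

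OsbZIP42 had by far the longest list. It held 28323 peaks, 25.6 times as many as OsbZIP69, with 1107 peaks, and 13.8 times as many as OsbZIP77, with 2059 peaks. The HALO-GST list, called without a control, held 194 peaks. The lists began at nearly the same signal, 9.0 for OsbZIP42, 9.2 for OsbZIP69 and 9.5 for OsbZIP77, and their medians were also close, at 24, 25.9 and 22. They differed at the top: the highest signal was 736 for OsbZIP42, 263 for OsbZIP69 and 99.0 for OsbZIP77. In the HALO-GST list the median signal was 6.0 and the highest 30. On all 12 chromosomes OsbZIP42 peaks outnumbered those of the other proteins, with densities between 61.4 peaks per Mb on chromosome 12 and 91.6 on chromosome 1. OsbZIP69 density ran from 2.36 per Mb on chromosome 9 to 3.42 on chromosome 5, and OsbZIP77 density from 4.23 on chromosome 4 to 6.89 on chromosome 1.

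Within 100 bp, the bZIP lists did not overlap the control beyond chance. A HALO-GST centre lay within 100 bp of 3 OsbZIP42 peaks, where shuffled positions gave 3.01 on average, of 0 OsbZIP69 peaks and of 1 OsbZIP77 peak, where shuffles reached 2 for each of the latter lists. For OsbZIP69, 0 of 1107 allows a share of up to 0.271% (3 counts of the total), by counting error only. None of the 1000 strongest OsbZIP42 peaks had a HALO-GST peak within 100 bp (0 of 1000, which allows a share of up to 0.300% by the same rule). The strongest HALO-GST peak, on chromosome 9 from 4706059 to 4706259, lay 20950 bp from the nearest OsbZIP42 peak. Since the bZIP peaks were called against a negative control, loci rich in control reads were discounted before these lists were made.

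The next comparison asked how far the 3 proteins occupied the same sites. Nearly every OsbZIP69 and OsbZIP77 site was also an OsbZIP42 site. Of the OsbZIP69 peaks, 1080 of 1107 lay within 100 bp of an OsbZIP42 peak, or 97.6% (95% interval 96.5 to 98.4). Of the OsbZIP77 peaks, 1985 of 2059 did, or 96.4% (95.5 to 97.2). Shuffling gave 16.4 and 30.7 shared peaks on average, and at most 30 and 49, so that 0 of 1000 shuffles reached either value. Moving each peak by 5 to 50 kb gave at most 36 and 55. Such moves keep the density of OsbZIP42 peaks over that distance, but not at the scale of the 100 bp window. OsbZIP69 and OsbZIP77 shared 815 of the 1107 OsbZIP69 peaks, or 73.6% (70.9 to 76.2), against 1.19 on average and at most 5 in shuffles. The centres were close: 934 OsbZIP69 and 1705 OsbZIP77 centres lay within 10 bp of an OsbZIP42 centre.

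**Figure D1:**
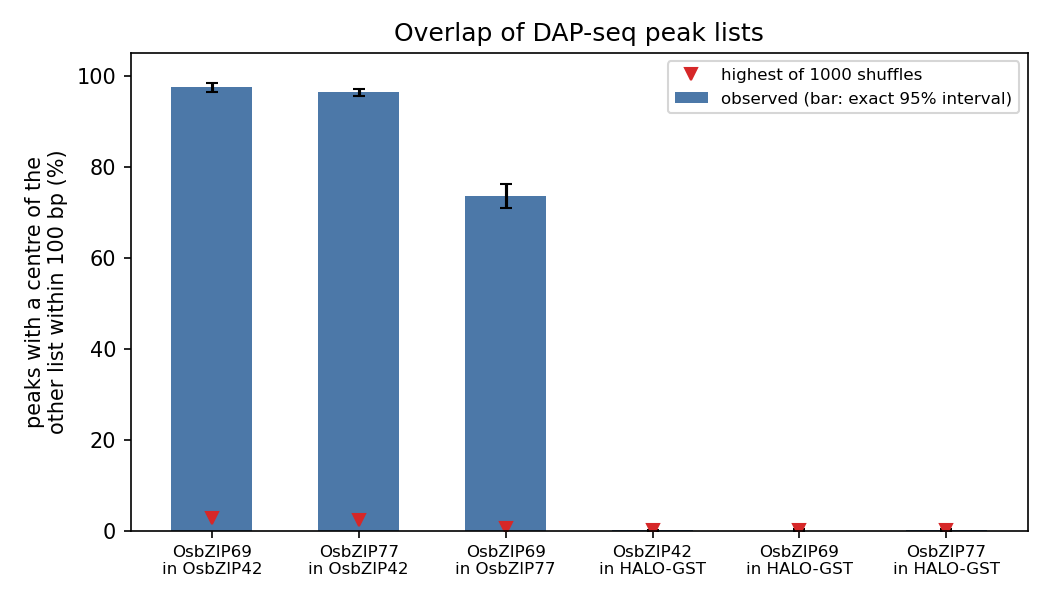
Share of the peaks of one list (first name, y axis in percent) with a centre of another list within 100 bp; bars show the observed share with its exact 95% interval and triangles the highest of 1000 shuffles. OsbZIP69 and OsbZIP77 reach 97.6% and 96.4% in the OsbZIP42 list, whereas none of the bZIP lists exceeds the shuffles in the HALO-GST list.

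The overlap was nested. All 815 OsbZIP69 peaks found with OsbZIP77 were also found with OsbZIP42, and 0 peaks were shared by OsbZIP69 and OsbZIP77 outside the OsbZIP42 list. A further 265 OsbZIP69 peaks were shared with OsbZIP42 alone and 27 were in neither other bZIP list. Of the OsbZIP77 peaks, 1171 were shared with OsbZIP42 alone and 74 were in neither. Conversely, 25825 OsbZIP42 peaks, or 91.2% (90.8 to 91.5), were in neither shorter list. The unshared peaks of the shorter lists were weak. Their median signal was 12 in OsbZIP69 and 13 in OsbZIP77, against 29 and 28 for peaks in all 3 lists, and 25 of the 27 and 71 of the 74 fell in the lower 50% of their list by signal. The strongest OsbZIP77 peak outside the OsbZIP42 list, on chromosome 1 from 39111644 to 39111844 with a signal of 47.0, was centred 48 bp from a HALO-GST peak. The strongest such OsbZIP69 peak, on chromosome 12 from 13388529 to 13388729, had a signal of 36.0 and lay 2930 bp from a HALO-GST peak. Over all such peaks, 1 of the 27 for OsbZIP69 and 1 of the 74 for OsbZIP77 lay within 1000 bp of a HALO-GST peak.

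The lists were also shortened to their 1107 strongest peaks. This kept every OsbZIP69 peak but only 1107 of the 28323 OsbZIP42 peaks and of the 2059 OsbZIP77 peaks. Lists of equal length can be nested only if they coincide, so the lower shares here do not bear on the nesting. OsbZIP69 then shared 405 peaks with OsbZIP42, or 36.6% (33.7 to 39.5), and OsbZIP77 shared 430, or 38.8% (36.0 to 41.8). OsbZIP69 and OsbZIP77 shared 630, or 56.9% (53.9 to 59.9), an interval above both others. All 3 values exceeded every shuffle.

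Sharing rose with the strength of the OsbZIP42 peak. OsbZIP69 had a peak at 26.8% (25.2 to 28.5) of the OsbZIP42 peaks in the top decile of signal, at 7.84% (6.88 to 8.89) in the second and at 0.459% (0.245 to 0.783) in the lowest. For OsbZIP77 these shares were 40.7% (38.9 to 42.5), 16.5% (15.2 to 17.9) and 0.741% (0.459 to 1.13). Of the 100 strongest OsbZIP42 peaks, 73 were in the OsbZIP69 list and 82 in the OsbZIP77 list. The shared OsbZIP69 peaks had a median rank at 6.75% of the OsbZIP42 list, and the shared OsbZIP77 peaks at 9.38%. Yet 42 shared OsbZIP69 peaks and 126 shared OsbZIP77 peaks matched an OsbZIP42 peak in the lower 50% of its list. Within the shorter lists the upper 50% by signal was shared more often with OsbZIP42 than the lower 50%, at 99.6% against 95.5% for OsbZIP69 (Fisher's exact test, two-sided, adjusted p = 4.46e-06) and at 99.7% against 93.1% for OsbZIP77 (Fisher's exact test, adjusted p = 3.03e-18).

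**Figure D2:**
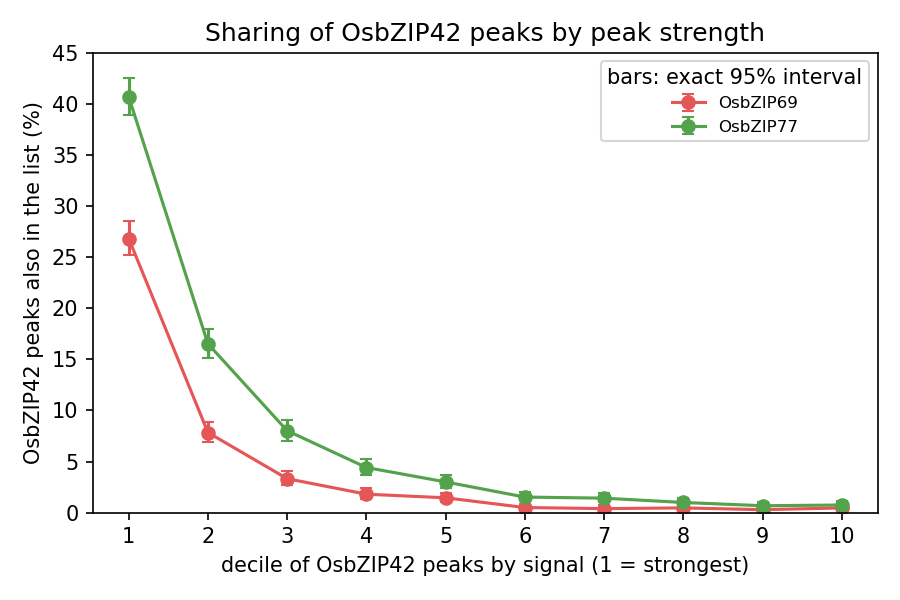
Share of OsbZIP42 peaks that were also in the OsbZIP69 or OsbZIP77 list (y axis, percent, exact 95% intervals) by decile of OsbZIP42 signal (x axis, 1 is the strongest). The share falls from 26.8% to 0.459% for OsbZIP69 and from 40.7% to 0.741% for OsbZIP77 between the first and last decile.

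OsbZIP69 and OsbZIP77 peaks fell together within strata of measured OsbZIP42 signal. Over OsbZIP42 peaks in 20 strata of signal, the odds of an OsbZIP77 peak were 15.9 times as high where OsbZIP69 also had a peak (95% interval 13.5 to 18.8). Each stratum spans a range of the signal measured in 1 unrepeated OsbZIP42 library. Differences in measured and in true strength within a stratum therefore remain in this value. In the strongest stratum, OsbZIP77 was present at 83.8% of the 445 OsbZIP42 peaks with OsbZIP69 and at 26.5% of the 972 without it. Measured signal in that stratum ran up to 736, and sharing varied with it. OsbZIP69 had a peak at 73.0% of the 100 strongest OsbZIP42 peaks and at 39.2% of the 1000 strongest. The shares of 83.8% and 26.5% thus do not compare peaks of equal signal. Across the 815 sites in all 3 lists, Spearman's rho of peak signal was 0.54 (bootstrap 95% interval 0.49 to 0.59) between OsbZIP69 and OsbZIP77, 0.36 (0.29 to 0.42) between OsbZIP42 and OsbZIP77, and 0.30 (0.23 to 0.36) between OsbZIP42 and OsbZIP69. Pearson's r of log2 signal was 0.59, 0.39 and 0.33 in that order. Each rho had a permutation p of 1e-05 and the same adjusted value, the smallest the permutations can give. The rho of OsbZIP69 with OsbZIP77 exceeded that of OsbZIP42 with OsbZIP69 by 0.25 (0.17 to 0.32) and that of OsbZIP42 with OsbZIP77 by 0.18 (0.11 to 0.26). These values run across sites of single libraries, and sites are not independent replicates. The 815 sites also cover the lists unequally. They hold 73.6% of the OsbZIP69 peaks, but OsbZIP42 peaks near both other lists were 3.31% of its list. The median signal of those OsbZIP42 peaks was 102, against 24 in its whole list. So narrow a part of the OsbZIP42 list may itself lower its rhos, so their order does not rank the proteins by likeness.

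**Figure D3:**
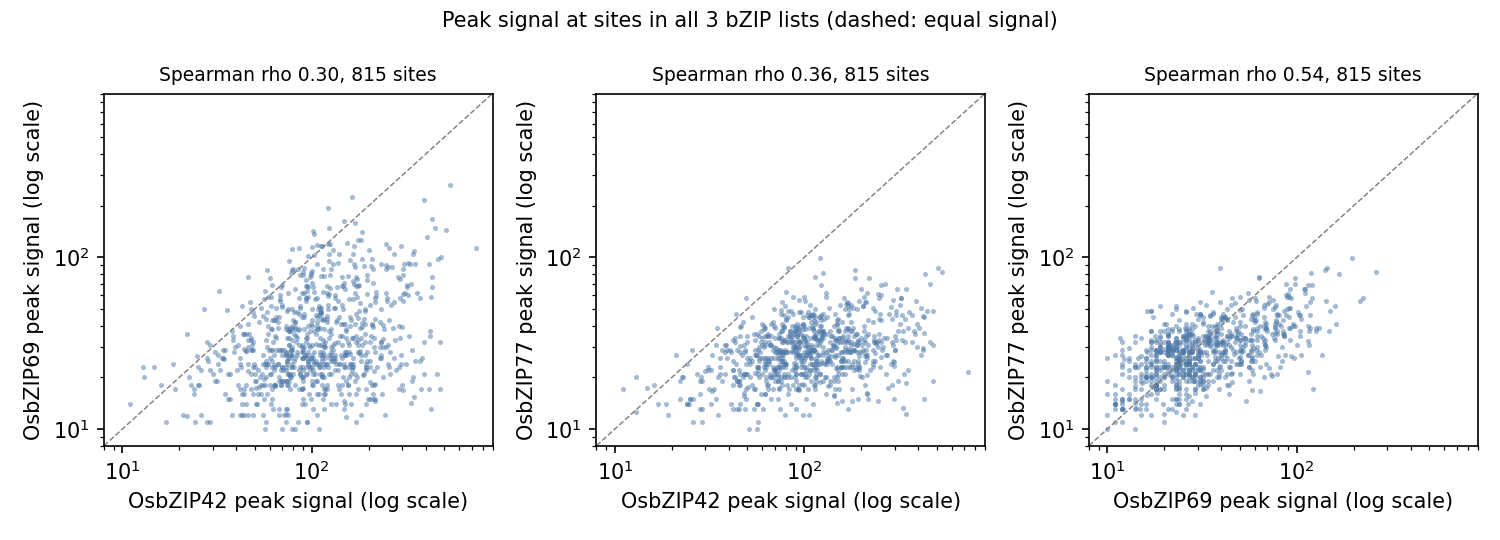
Peak signal of 2 proteins at each of the 815 sites in all 3 bZIP lists, on log axes in the authors' signal units; each point is a site and the dashed line marks equal signal. Points follow each other most closely for OsbZIP69 and OsbZIP77 (rho 0.54) and lie mostly below the line against OsbZIP42. The sites cover only a small, strong part of the OsbZIP42 list, which may lower its rhos.

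Several sites were among the strongest for every protein. The site with the best worst rank lay on chromosome 12 from 17464091 to 17464291. It was the strongest OsbZIP69 peak, with a signal of 263, ranked 2 for OsbZIP42 with 535 and ranked 4 for OsbZIP77 with 82.0. The site on chromosome 10 from 22328279 to 22328479 ranked 11 for OsbZIP42, 5 for OsbZIP69 and 6 for OsbZIP77. The site on chromosome 9 from 17092454 to 17092654 ranked 3, 10 and 2 in the same order, with signals of 509, 144 and 87.0. The site on chromosome 7 from 11384541 to 11384741 ranked 383 for OsbZIP42, 12 for OsbZIP69 and 3 for OsbZIP77, within the top 1.35%, 1.08% and 0.146% of those lists. The other 6 of the 10 best common sites, given as OsbZIP69 intervals, lay on chromosome 2 (23448159 to 23448359), chromosome 5 (13708789 to 13708989, and 27690492 to 27690692), chromosome 7 (12926088 to 12926288), chromosome 10 (19729183 to 19729383) and chromosome 12 (24465091 to 24465291). Each of the 10 was within the top 2.53% of all 3 lists. The site on chromosome 7 from 12926088 to 12926288 was the OsbZIP69 peak of rank 2, with signals of 224 for OsbZIP69, 163 for OsbZIP42 and 58.0 for OsbZIP77. One of them, on chromosome 5, belonged to a group of 4 OsbZIP42 peaks with centres at 13708722, 13708773, 13708890 and 13708971 and signals of 367, 425, 390 and 150. OsbZIP69 had centres there at 13708760 and 13708889, with signals of 59.1 and 215. OsbZIP77 had centres at 13708723 and 13708888, with signals of 29.6 and 55.4.

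**Figure D4:**
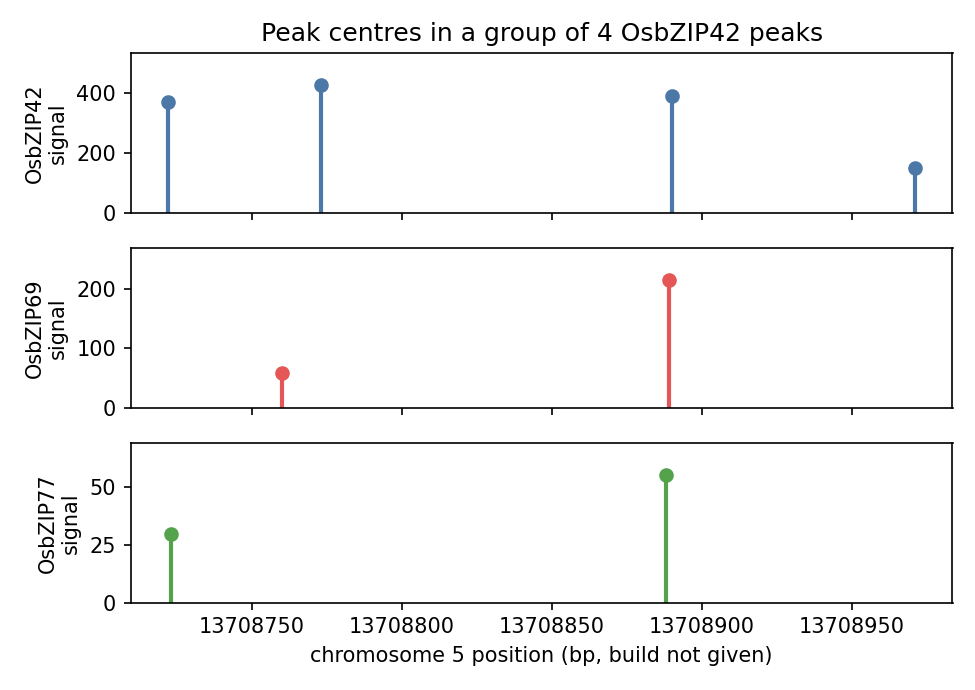
Centres (x axis, bp) and signals (y axis, authors' units, a scale of its own per panel) of the peaks of each protein around a group of 4 OsbZIP42 peaks on chromosome 5. OsbZIP42 had signals of 367, 425, 390 and 150, and the strongest OsbZIP69 and OsbZIP77 peaks, at 215 and 55.4, were centred within 2 bp of the third of these centres.

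Other leading sites of one protein are given with their place in each list, as a share of its length, since the lists differ in length and such places do not measure a change. The strongest OsbZIP42 peak, on chromosome 5 from 2080919 to 2081119, had a signal of 736. At it, OsbZIP69 had a peak with a signal of 114, in the top 2.44% of its list. OsbZIP77 had a pair of peaks within 100 bp, with signals of 25.1 and 21.5, at 35.3% and 52.0% of its list. The OsbZIP42 peaks of rank 4 and 5, on chromosome 12 from 24058804 to 24059004 and from 20903600 to 20903800, had signals of 480 and 478. They stood at 3.70% and 35.8% of the OsbZIP69 list and at 20.5% and 65.9% of the OsbZIP77 list. The strongest OsbZIP77 peak, on chromosome 12 from 23129480 to 23129680, was in the top 0.361% of the OsbZIP69 list and the top 3.68% of the OsbZIP42 list. The OsbZIP77 peak of rank 5, on chromosome 2 from 27553445 to 27553645, was in the top 1.81% and 3.46% of those lists. The strongest OsbZIP42 peak without an OsbZIP69 peak, chosen after its values were seen, lay on chromosome 11 from 20549354 to 20549554 with a signal of 464 against 19.0 for OsbZIP77. The strongest in neither shorter list, chosen likewise, lay on chromosome 4 from 6925865 to 6926065 with a signal of 369.

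At shared sites the signal was usually lower for the shorter lists. The median ratio to the OsbZIP42 signal was 0.319 for OsbZIP69 over 1080 sites and 0.305 for OsbZIP77 over 1985 sites. The log2 ratio had an SD across sites of 1.06 for OsbZIP69 and 0.90 for OsbZIP77, and it departed by more than 2 from its median at 63 and 48 sites. Each site is a peak of the shorter list with the nearest OsbZIP42 centre within 100 bp, so 1 OsbZIP42 peak can count repeatedly. The strongest OsbZIP42 peak was counted with both OsbZIP77 peaks near it, 31 and 21 bp away. Split or off-centre peaks therefore add to the spread. OsbZIP69 exceeded OsbZIP42 in signal at 58 sites and OsbZIP77 did at 31. Because the unit of the signal and its scaling between libraries are not stated and no library was repeated, it remains unknown how much of this spread repeat libraries of one protein would show.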

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

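Of 61 alternatives for 19 results, 46 were fixed before the data were examined and 15 were added later; 56 kept their direction and their side of the threshold, or stayed within 1.5 times the main count. The other 5 follow from keeping the upper 50% of each list by q-value, which by construction left 14161, 553, 1029 and 97 peaks for OsbZIP42, OsbZIP69, OsbZIP77 and HALO-GST, and 411 sites in all 3 lists. Windows from 50 to 500 bp moved the share of OsbZIP69 peaks in the OsbZIP42 list between 96.0% and 98.2% and that of OsbZIP77 peaks between 94.2% and 97.1%. Lists of equal length kept all 3 overlaps above every shuffle but lowered the OsbZIP69 and OsbZIP77 shares to 36.6% and 38.8%. Leaving out peaks near HALO-GST peaks removed 3 OsbZIP42, 0 OsbZIP69 and 1 OsbZIP77 peaks, so those alternatives could hardly alter a result. The odds ratio between OsbZIP69 and OsbZIP77 stayed between 15.7 and 16.9 under 10 or 50 strata and windows of 50 or 500 bp. Restricting sites to centres within 10 bp in all 3 lists left 656 sites and gave rho of 0.57 between OsbZIP69 and OsbZIP77, 0.38 between OsbZIP42 and OsbZIP77 and 0.33 between OsbZIP42 and OsbZIP69. No alternative could leave out a replicate. No paired analysis was possible because each protein had 1 library. The alternatives for genomic distribution, motifs, k-mers, gene lists and target genes were not run, as no genome or annotation of the files' build was used here. Unknown depth limits any statement on peaks absent from the shorter lists.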

Other observations

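The tests in this part were chosen after the overlaps had been seen. For the 2 tests on the 1 bp displacement, which is itself seen only in matched lists, the predictions were written before their results.

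Peak centres lay close together more often than moved peaks did. In the OsbZIP42 list 1009 neighbouring pairs of centres lay within 100 bp, against 258 on average and at most 295 when peaks were moved by 5 to 50 kb. OsbZIP69 had 18 such pairs against at most 3, and OsbZIP77 had 14 against at most 6. With gaps of up to 200 bp, 1704 groups of OsbZIP42 held 2 centres, 87 held 3 and 5 held 4. The group with the highest summed signal was the one on chromosome 5 described above. Neighbouring sites were not told apart here from a single enriched region that the caller split into several peaks. Over whole 1 Mb intervals, the number of OsbZIP42 peaks ranged from 15, on chromosome 4 from 9 to 10 Mb and on chromosome 11 from 12 to 13 Mb, to 144 on chromosome 1 from 1 to 2 Mb, with a median of 77.5. These counts are not corrected for repeats, where reads that map to several places seem to have been left out. Counting only the OsbZIP42 peak nearest to each peak of the other list, the share found with OsbZIP69 was 3.75% (95% interval 3.37 to 4.15) where the whole 1 Mb interval held 15 to 75 OsbZIP42 peaks, 4.14% (3.74 to 4.57) where it held 76 to 98 and 3.55% (3.18 to 3.95) where it held 99 to 144. With OsbZIP77 these shares were 6.20% (5.71 to 6.71), 7.74% (7.20 to 8.30) and 7.02% (6.51 to 7.57).

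Chromosomes differed in how often an OsbZIP42 peak was shared, by the same count of nearest peaks. With OsbZIP69 the share ran from 2.99% on chromosome 9 and 3.11% on chromosome 3 to 4.80% on chromosome 12 and 5.14% on chromosome 11 (permutation test over 12 chromosomes, p = 0.00184, adjusted 0.00184). With OsbZIP77 it ran from 5.63% on chromosome 9 to 8.41% on chromosome 12 (permutation test, p = 0.00138, adjusted 0.00184). A permutation test within 20 strata of OsbZIP42 signal gave p = 0.00247 for OsbZIP69 and 0.0032 for OsbZIP77, each with an adjusted p of 0.0032. Both tests treated OsbZIP42 peaks as independent, although their centres clustered, with 1009 neighbouring pairs within 100 bp against 258 on average for moved peaks. The p-values do not allow for that clustering. The share also depends on the number of OsbZIP42 peaks, which was lowest per Mb on chromosomes 12 and 11, at 61.4 and 63.7. OsbZIP69 density there was 3.09 and 3.41 per Mb, against 3.14 on chromosome 1, where the share was 3.31%.

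The first pattern weighed is the nesting of the OsbZIP69 and OsbZIP77 lists in that of OsbZIP42. Chance overlap from local peak density is argued against by the local moves, which gave at most 36 shared OsbZIP69 peaks where 1080 were observed. Reads carried over from the OsbZIP42 library, as the source of all or some of the peaks, stay open. At a given OsbZIP42 signal the partial Spearman correlation of OsbZIP69 and OsbZIP77 signal was 0.488 (bootstrap 95% interval 0.430 to 0.541), but carry-over predicts 0 only if the OsbZIP42 signal had no error, and 1 library does not give that error. Carry-over between the 2 shorter libraries, and a negative control library common to all 3 calls stay open too, since the reads were not analysed here. DNA preferences common to the 3 proteins, the explanation the design names, stay open and untested, because no sequence was searched.

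The second pattern is a displacement of exactly 1 bp. Of the 934 OsbZIP69 centres within 10 bp of an OsbZIP42 centre, 866 were 1 bp away and 0 coincided, and of 1705 OsbZIP77 centres 1593 were 1 bp away, whereas 702 of 720 OsbZIP69 centres coincided with an OsbZIP77 centre. A fixed coordinate shift between files is argued against, since 433 displacements went to higher and 433 to lower coordinates, or 50% (46.6 to 53.4). The share at 1 bp was 93.3% in the upper and 92.1% in the lower 50% of OsbZIP69 peaks by signal, a change of -1.12 percentage points. Centres that the caller placed on a sequence anchor, with another reference base in the OsbZIP42 run, would give such a stable share. Any other displacement that does not depend on signal would give it too, and no sequence was searched, so the share does not favour the anchor. If the caller did place the centres so, their closeness may reflect the caller as much as the reads.

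The third pattern is the length of the OsbZIP42 list. Weaker enrichment in the shorter libraries, or fewer usable reads if signal was not scaled for depth, could lower signal at shared sites. Whether signal was scaled is not stated. The median ratio of OsbZIP69 to OsbZIP42 signal was 0.319 (bootstrap 95% interval 0.298 to 0.343). Fewer reads or weaker enrichment cannot be told apart from a difference between the proteins. Each protein had 1 library of unknown depth, and the shared sites were those that passed in both. The share of 36.6% among equally long lists shows that the OsbZIP69 list was not simply the strongest OsbZIP42 peaks. The same holds for the OsbZIP77 list of 2059, which included only 54.5% of the 1000 strongest OsbZIP42 peaks. Without repeat libraries the part owed to noise is unknown for both lists.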
